A study of Mus musculus with 12 samples.

How the data were processed

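Gene expression was measured by RNA sequencing in OT-I cells, CD8 T cells whose transgenic receptor recognises a peptide of ovalbumin. The cells were Rroid2 wild-type (WT) or Rroid2 knockout (KO), had been transferred into mice infected with *Listeria monocytogenes* expressing ovalbumin, and were sorted from spleen. SLEC are short-lived effector cells and MPEC are memory precursor effector cells; by convention SLEC are high for KLRG1 and low for CD127, the protein of *Il7r*, while the gates used are not given in the sources used here. Per the labels, RNA was extracted with a column kit for small samples and made into stranded SMART-Seq libraries. The 12 libraries form 6 groups of 2: WT and KO SLEC on day 7, WT and KO SLEC on day 14, and WT and KO MPEC on day 14.

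The deposited table holds raw read counts per gene. Per the submitters' processing notes the authors demultiplexed with bcl2fastq and aligned with STAR 2.6.1a to GRCm38; the counting program, annotation release and strand setting are not given in the sources used here. All values were checked to be whole numbers. The table has 55421 genes, and 55154 of their identifiers (99.5%) were found in a GENCODE annotation of GRCm38, from which positions were taken. For 27 genes the symbol was a date serial number and was restored through the identifier. Columns were matched to groups from the labels; the accompanying sample sheet holds no measurement and was not used here. No library was left out.

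Total counts per library ran from 7603551 (KO SLEC day 14 replicate 2) to 14026594 (WT SLEC day 7 replicate 1), so a count of 3 in a library lies well under 1 CPM. Limits from counts cover counting error only, since reads without molecular identifiers are not independent molecules. The labels do not say whether the 2 libraries of a group come from separate animals, so the p-values of genes measure only the spread between libraries. Camera at the preset correlation compares a list with other genes, and the permutation p-values come from random draws of genes. Neither stands for the spread between animals.

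Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept with filterByExpr over the 6 groups, which left 14460 genes holding 99.7% or more of the counts of each library, and libraries were scaled with trimmed mean of M-values factors. A quasi-likelihood model with 1 coefficient per group was fitted to all 12 libraries, with robust shrinkage and bias-adjusted deviances, leaving 6 residual degrees of freedom and a median of 11.9 prior degrees of freedom. There were 10 comparisons: KO against WT in each of the 3 populations and as their mean, the difference of the KO effect between days and between populations, day 14 against day 7 in SLEC of each genotype, and MPEC against SLEC at day 14 in each genotype. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 within a comparison. The tests of genes and of gene lists are two-sided, and the permutation p-values are one-sided. Log2 changes are given with their standard error (SE), and levels as CPM (counts scaled to the library size) with the standard deviation (SD). Principal components used log2 CPM with a prior count of 2 for the 2000 most variable genes.

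Sets of genes were tested with camera of limma 3.58.1 at a preset correlation between genes of 0.01, again with the correlation estimated from the data, and with fry; fry called 0 of the 25 T cell lists in every KO effect. There were 25 lists of T cell biology and 11 lists of marker genes of other cells, and p-values were adjusted over the lists of each kind within a comparison; lists with fewer than 5 tested genes were given as summed CPM only. Where a group had 0 counts for a gene, a fold was bounded against a floor of 3 counts over the group. Signatures, the genes called between WT populations, were tested in the KO effect of a population whose libraries had not defined them.

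Genes were named by a rule. In each comparison these were the 12 genes with the largest rise and the 12 with the largest fall among called genes with a mean log2 CPM of 3 or more and with both libraries of 1 group above both of the other, or the same sign in the 3 populations for the mean. Where fewer than 10 genes passed, the 5 genes per direction with the smallest unadjusted p were added. From each T cell list up to 4 called members and up to 2 others with the smallest p were taken, and *Id2*, *Id3*, *Klrg1*, *Il7r*, *Tcf7*, *Tbx21*, *Zeb2*, *Eomes*, *Gzmb* and *Bcl2* were followed throughout. A few genes that the rule names are not reported here. Predicted genes, receptor and immunoglobulin segments and pseudogenes with a symbol ending in -ps were counted but not named by it, while *Ptprv*, a polymorphic pseudogene by its annotation, was named, as the rule goes by symbol; the exceptions below were chosen after their values were seen. The groups, comparisons, lists, naming rule and most alternatives were fixed before the data were examined.

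Alternatives were DESeq2-style size factors, no filter on low counts, a filter at 5 CPM in 2 libraries, the older quasi-likelihood method, a block for replicate number (overall or by day), a fit of only the groups compared, limma-voom, the Wald test of DESeq2 1.42.0, and leaving out each library in turn. With 1 library left out, the group's other library was assumed to vary like the other groups, and the 14460 genes were kept as they were; the first version filtered anew each time, which changed 2 choices at once, and was replaced after its output was seen. A term for the B cell RNA of each library, protein-coding genes alone, and a mean without SLEC day 14 were chosen after seeing the data. The procedure was tested on simulated data. With 2 libraries against 2, as in SLEC day 14, it recovered 41.8% of 2-fold, 61.2% of 4-fold and 71.2% of 8-fold changes, with 6 unchanged genes called. For the mean of 3 populations it recovered 67.2%, 79.1% and 87.9%, with 19 unchanged genes called beside 156 changed ones.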

Results

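RNA of sorted OT-I cells was compared between Rroid2 WT and KO cells in 3 populations, SLEC on day 7, SLEC on day 14 and MPEC on day 14, with 2 libraries in each of the 6 groups. Total counts were 14026594 and 12346072 in WT SLEC day 7, 13533933 and 11380423 in KO SLEC day 7, and 12427019 and 13740911 in WT SLEC day 14. They were 9507830 and 7603551 in KO SLEC day 14, 12665122 and 10951559 in WT MPEC, and 9659158 and 10950082 in KO MPEC. *Cd8a* had 69972 counts over the WT and 53034 over the KO libraries, and *Cd4* had 40 and 15. Mitochondrial ribosomal RNA took 8.0% to 19.5% of a library's counts and long non-coding RNA 4.82% to 11.8%. Between 16088 and 25372 genes were detected, the most in WT SLEC day 14 replicate 2. Across genes, the Spearman correlation between the replicates of a group was 0.966 to 0.981. The variance of counts between replicates was 12.8 to 72.9 times that of counting error alone (chi-square per degree of freedom), most in WT SLEC day 7. This ratio weighs genes with high counts most. The first principal component held 39.0% of the variance and ordered the libraries from SLEC day 7 (39.5 to 57.9) through SLEC day 14 (-16.5 to 2.85) to MPEC (-51.5 to -34.5). The second held 20.5% and set the WT SLEC day 14 libraries (54.0 and 67.2) apart from the others.

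**Figure D1:**
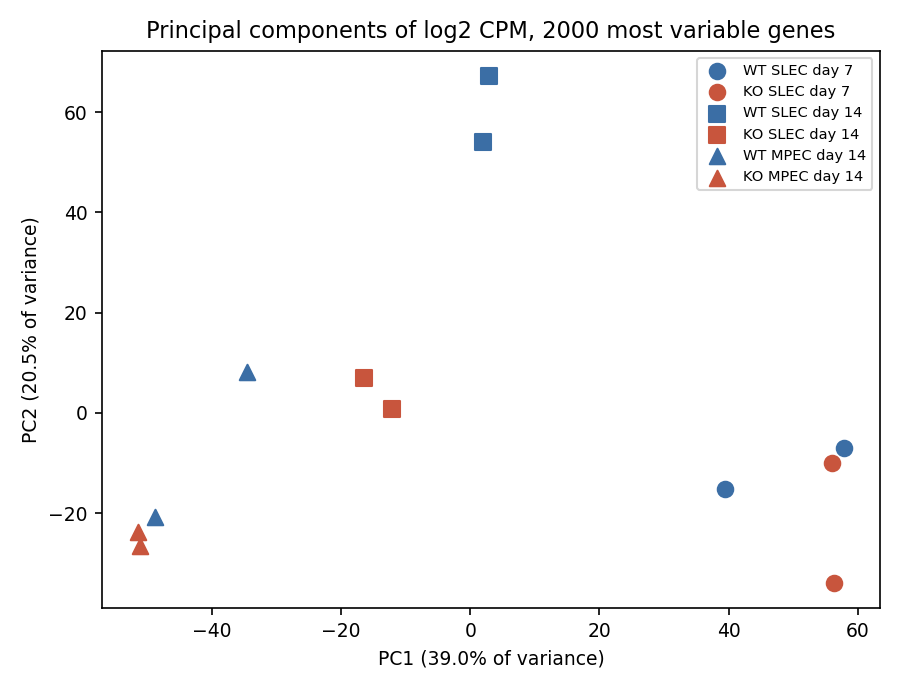
Principal components of log2 CPM of the 2000 most variable genes; each point is a library, coloured by genotype and shaped by population, and the axes give the share of variance (39.0% and 20.5%). The WT SLEC day 14 libraries lie at 54.0 and 67.2 on the second component.

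Genes of other cells were measured in every library, because a sorted population can carry their RNA. The 17 genes of the B cell list summed to 1018 and 3772 CPM in the WT SLEC day 14 libraries, against 26.7 to 465.5 CPM in the other 10. Within WT MPEC the sum was 465.5 CPM in replicate 1 and 145 CPM in replicate 2. Plasma cell genes summed to 74.0 and 23.9 CPM in WT SLEC day 14 and to 0.210 to 5.13 CPM elsewhere. Monocyte and macrophage genes reached 100.7 and 81.7 CPM there and 11.3 to 61.5 CPM elsewhere. Neutrophil genes reached 90.3 CPM in WT SLEC day 14 replicate 1 and 12.2 CPM in replicate 2, with at most 8.76 CPM elsewhere. Erythroid genes summed to 110.3 CPM in KO SLEC day 7 replicate 1 and to 0 to 37.2 CPM elsewhere. Platelet genes (2.47 to 13.8 CPM), dendritic cell genes (161 to 622 CPM), CD4 T cell genes (66.2 to 155 CPM) and gamma delta T cell genes (41.8 to 137 CPM) were present in all libraries. *Cd4* itself had at most 14 counts in a library (WT MPEC replicate 1, 1.11 CPM), so the CD4 list sums come almost wholly from its other members. The dendritic list holds *Itgax*, *Bst2*, *Tcf4* and *Ccr9*, which are also in the lists of T cell biology. Sums of the dendritic and CD4 lists alone are therefore no sign of other cells. The NK cell list (142 to 3371 CPM) holds *Gzma* and the stroma list (499.5 to 2473 CPM) holds *Vim*, both also expressed by effector T cells.

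**Figure D2:**
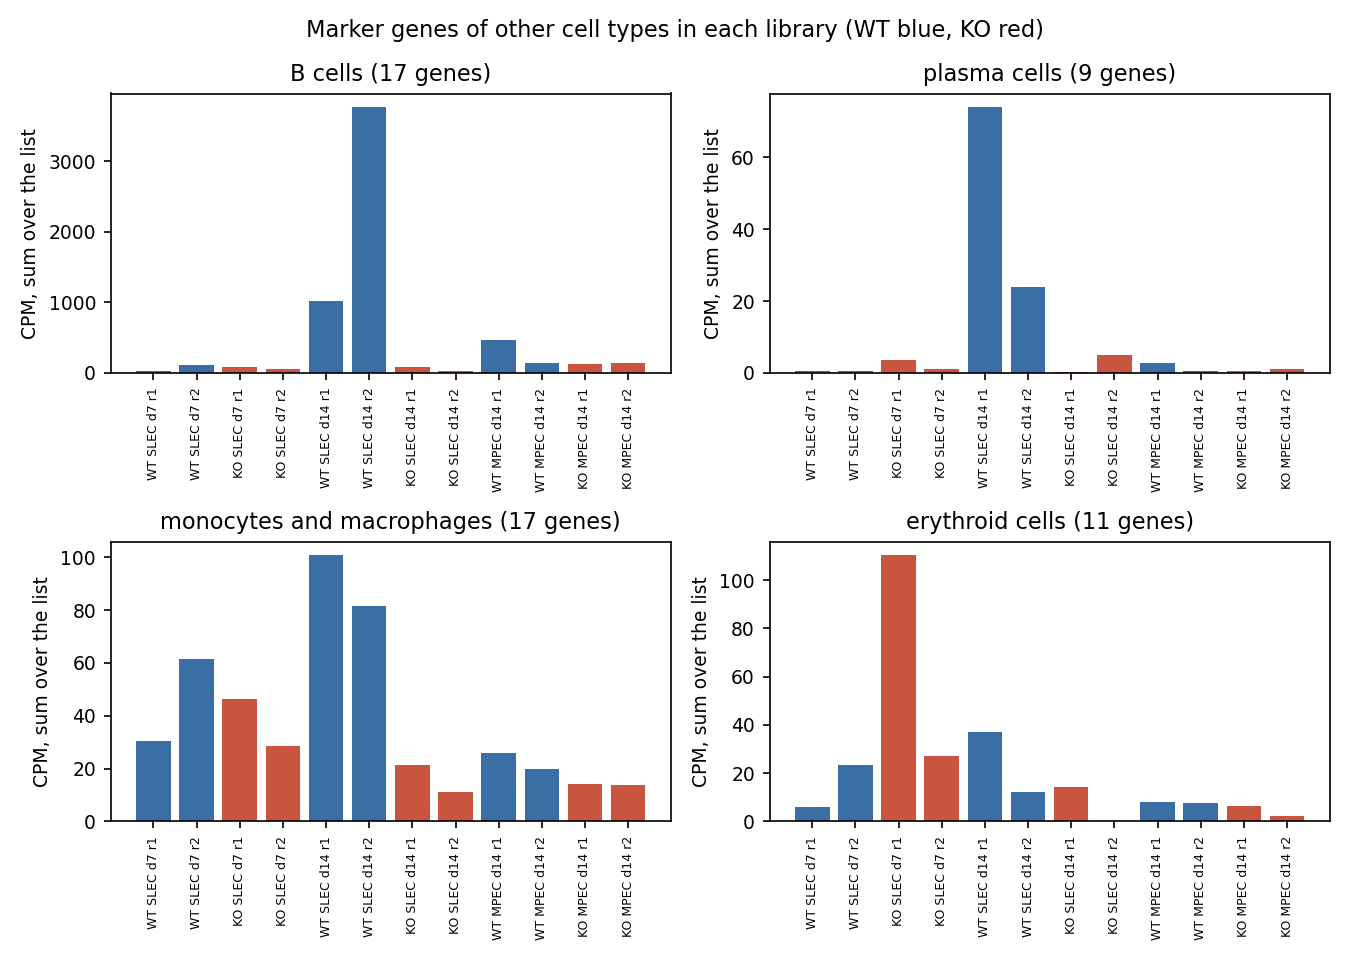
Summed CPM of marker genes of B cells, plasma cells, monocytes and macrophages, and erythroid cells, as a bar per library, WT in blue and KO in red. The B cell sums of the WT SLEC day 14 libraries were 1018 and 3772 CPM, above the other 10.

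No gene in the table or the annotation bore the symbol Rroid2, so loss of the targeted RNA could not be read from a count. By its name, and from general knowledge, Rroid2 is a non-coding locus in the neighbourhood of *Id2*, which encodes an inhibitor of E protein transcription factors needed by effector CD8 T cells; its position is not given in the sources used here. *Id2* (ENSMUSG00000020644.9, chromosome 12, 25093799 to 25097140, minus strand) was at 348 ± 65.4 CPM in WT and 418 ± 38.4 CPM in KO SLEC on day 7 (SD, n = 2). It was at 326.5 ± 33.7 and 279 ± 79.2 CPM in SLEC on day 14, and at 340.8 ± 22.4 and 327 ± 9.96 CPM in MPEC. The log2 change between KO and WT was 0.27 ± 0.18 (SE), -0.22 ± 0.18 and -0.06 ± 0.18 in the 3 populations and 0.00 ± 0.10 as their mean, and none of these passed the test. The neighbouring non-coding genes *Gm36723* and *Gm47701*, singled out after their values were seen, had a log2 change of 0.03 ± 0.24 and -0.46 ± 0.48 in the mean KO effect, and *Kidins220*, a protein-coding neighbour, 0.02 ± 0.09; none was called (adjusted p = 1.00, 0.86 and 0.99). Within 10 Mb of *Id2*, 7.25% of 69 tested genes had an unadjusted p under 0.05 in the mean KO effect, against 8.26% of all genes, and 1 was called, *Gm48904*. *Xist* had 62017 counts over the WT and 51741 over the KO libraries, and *Kdm5d*, *Eif2s3y*, *Uty* and *Ddx3y* on the Y chromosome had 0 to 4 in each genotype.

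The KO effect averaged over the 3 populations can be carried by 1 of them, and of the genes called in it *Ctse* alone was called in each population. *Ctse*, the gene of the aspartic protease cathepsin E (ENSMUSG00000004552.16, chromosome 1, 131638306 to 131675505, plus strand), showed the most certain difference. It was at 110.5 ± 0.799 CPM in WT and 18.5 ± 1.97 CPM in KO SLEC on day 7, at 97.4 ± 3.02 and 15.8 ± 1.79 CPM on day 14, and at 129 ± 21.2 and 18.9 ± 0.767 CPM in MPEC (SD, n = 2). *Ptprv*, a receptor tyrosine phosphatase gene annotated as a polymorphic pseudogene (ENSMUSG00000097993.7, chromosome 1, 135108497 to 135132594), was at 33.7 ± 3.19 and 6.66 ± 3.21 CPM, 39.05 ± 9.21 and 3.67 ± 1.11 CPM, and 15.03 ± 0.862 and 6.36 ± 1.30 CPM. *Mfsd14b*, a transporter gene of the major facilitator family (ENSMUSG00000038212.16, chromosome 13, 65064663 to 65112975), was higher in KO, at 84.3 ± 17.3 against 170.7 ± 19.7 CPM, 78.3 ± 0.985 against 200.9 ± 27.2 CPM, and 46.25 ± 2.28 against 84.6 ± 8.11 CPM. *Synj2*, which encodes an inositol phosphatase (ENSMUSG00000023805.17, chromosome 17, 5941280 to 6044290), was also higher in KO, at 7.6 ± 1.64 against 15.4 ± 2.36 CPM, 7.19 ± 0.238 against 17.6 ± 3.53 CPM, and 6.44 ± 0.183 against 34.2 ± 4.81 CPM. For these 4 genes both KO libraries lay beyond both WT libraries in every population.

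In the mean over the 3 populations, 12 genes were called, 6 higher and 6 lower in KO (28 and 61 by DESeq2, 53 and 114 without a filter on low counts), and 1195 genes had an unadjusted p under 0.05 where chance gives 723. The log2 change was -2.65 ± 0.11 for *Ctse* (adjusted p = 3.4e-11), -2.30 ± 0.19 for *Ptprv* (adjusted p = 4.5e-06), 1.08 ± 0.10 for *Mfsd14b* (adjusted p = 1.1e-05) and 1.57 ± 0.16 for *Synj2* (adjusted p = 7.2e-05). *Als2cl* fell by 1.23 ± 0.16 (adjusted p = 0.0011). *Wdfy1*, an adaptor in Toll-like receptor signalling, fell by 0.83 ± 0.13 (adjusted p = 0.012), and *Eps8l1* by 0.80 ± 0.14 (adjusted p = 0.021). *mt-Nd6*, the complex I subunit encoded on the light strand of mitochondrial DNA, rose by 0.56 ± 0.09 (adjusted p = 0.020). *Ctse*, *Ptprv*, *Mfsd14b*, *Synj2* and *Als2cl* kept their call whichever library was left out. *Wdfy1* lost it without KO SLEC day 14 replicate 1, WT MPEC replicate 1 or either KO MPEC library (adjusted p up to 0.085), while *mt-Nd6* lost it in 7 of the 12 omissions (up to 0.18) and *Eps8l1* in 8 (up to 0.19), most without WT MPEC replicate 1. The other 4 genes fall outside the naming rule and are given after their values were seen. *Ola1* was called in SLEC day 7 and not in SLEC day 14 or MPEC (adjusted p 0.17 and 1), *Gm9522* and *Gm48904* were higher by 2.18 and 1.38, and the pseudogene *Tmem181c-ps* had 217 counts over the WT and 2 over the KO libraries. With a term for B cell RNA, chosen after seeing the data, 6 of the 12 kept their call. The other 6 lost it with larger errors: the log2 change with the term was -0.93 ± 0.21 for *Wdfy1* (adjusted p = 0.23), 2.18 ± 0.69 for *Gm9522* (0.63) and 1.44 ± 0.44 for *Gm48904* (0.59). It was smaller for *Eps8l1* (-0.56 ± 0.21, adjusted p = 0.73), *mt-Nd6* (0.42 ± 0.15, 0.73) and *Ola1* (1.59 ± 0.28 against 1.92 ± 0.17 without the term, 0.14). Over these 6 genes the median size of the change was 1.11 without and 1.18 with the term, and the median SE 0.15 and 0.24. *Il7r* (0.51 ± 0.14, adjusted p = 0.31), *Map4k2* (adjusted p = 0.081) and *Gramd1a* (0.097) were not called. Leaving out WT SLEC day 7 replicate 2 gave 59 called genes, and leaving out WT MPEC replicate 1 gave 7.

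**Figure D3:**
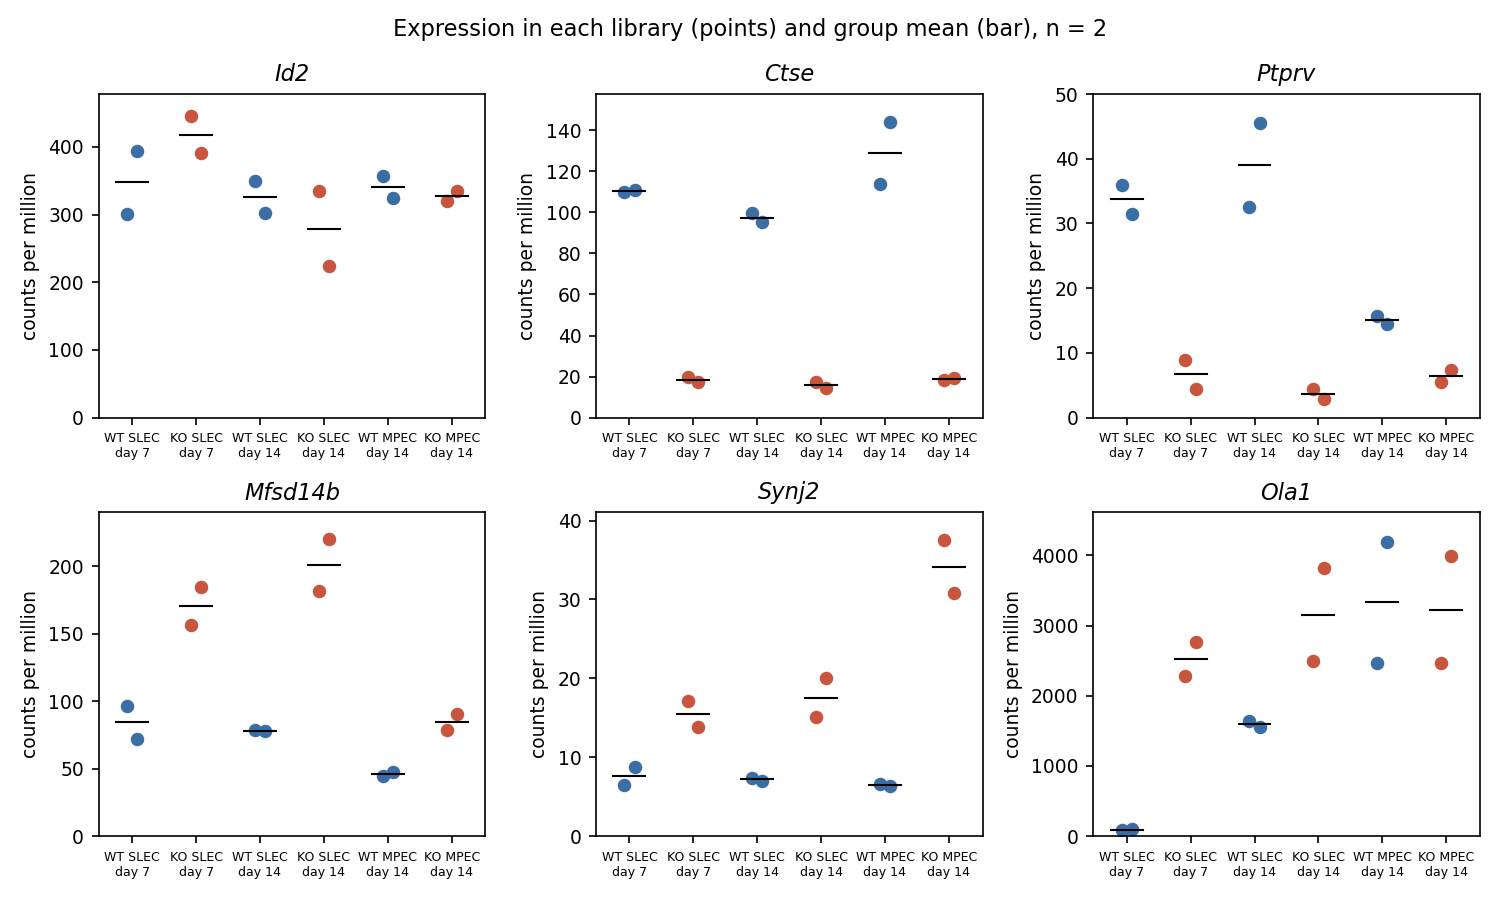
CPM of *Id2*, *Ctse*, *Ptprv*, *Mfsd14b*, *Synj2* and *Ola1* by group, with a point per library (WT blue, KO red), a bar at the group mean and axes that start at 0. *Ctse* was at 97.4 to 129 CPM on average in WT groups and at 15.8 to 18.9 CPM in KO groups.

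Of the 25 T cell lists, the mitochondrially encoded respiratory chain passed camera in the mean KO effect: all 7 genes were higher, with a median log2 change of 0.36 (adjusted p = 4.8e-12), but the adjusted p was 0.49 with an estimated correlation. The share of mitochondrial ribosomal RNA was also higher in both KO libraries of SLEC day 14, while on day 7 and in MPEC the libraries of the genotypes overlapped. Within the list 1 gene was called over all genes and 7 when adjusted over the list alone. Lists of other cells were lower in KO, with an adjusted p of 3.2e-13 for B cells (0.19 with an estimated correlation), 6.9e-10 for monocytes and macrophages (0.079) and 0.041 for dendritic cells (0.19).

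On day 7, 4 genes differed between KO and WT SLEC. *Ola1*, which encodes an ATPase of the Obg family (ENSMUSG00000027108.15, chromosome 2, 73092801 to 73218924), was at 88.6 ± 9.84 CPM in WT and at 2524 ± 339 CPM in KO (SD, n = 2). That is a log2 change of 4.83 ± 0.34 (SE, adjusted p = 1.7e-04). *Ctse* fell by 2.57 ± 0.18 (adjusted p = 4.7e-07) and *Ptprv* by 2.29 ± 0.30 (adjusted p = 0.0025), while *Mfsd14b* rose by 1.02 ± 0.17 (adjusted p = 0.037). *Als2cl* (-1.45 ± 0.29, adjusted p = 0.21), *Hdgfl3* (-0.80 ± 0.18, adjusted p = 0.61), the matrix protein gene *Thbs1* (1.81 ± 0.43, adjusted p = 0.76), the interferon-induced gene *Rsad2* (2.09 ± 0.52, adjusted p = 0.92) and the transcription factor gene *Maf* (1.16 ± 0.34, adjusted p = 1) were not called. Nor were the markers of effector state *Klrg1* (-0.19 ± 0.19), *Zeb2* (-0.33 ± 0.22), *Gzmb* (0.25 ± 0.31), *Tbx21* (-0.06 ± 0.18) and *S1pr5* (-0.47 ± 0.22), nor *Il7r* (0.34 ± 0.27), *Tcf7* (0.39 ± 0.69), *Bcl2* (0.03 ± 0.28) and *Eomes* (0.51 ± 0.54). In all, 488 genes had an unadjusted p under 0.05, below the 723 that chance gives. *Ctse* kept its call whichever library was left out. *Ola1* lost it without WT SLEC day 7 replicate 1 (adjusted p = 0.074), *Ptprv* without KO SLEC day 7 replicate 2 (0.092), and *Mfsd14b* when any of the 10 libraries outside WT SLEC day 7 was left out (up to 0.62). Without WT SLEC day 7 replicate 2 the count was 198, and without KO SLEC day 7 replicate 2 it was 2.

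On day 7, 6 T cell lists passed camera at the preset correlation in SLEC, but none with an estimated correlation (adjusted p 0.91 to 0.98) or by fry (1), and edgeR called 0 of their genes over all genes tested. Of the genes of G2 and M phase, 29 of 30 had a positive change, with a median of 0.35 (adjusted p = 1.5e-05 by camera). All 7 mitochondrially encoded respiratory chain genes were higher, with a median of 0.46 (adjusted p = 8.3e-09; mitochondrial ribosomal RNA took 18.3% and 12.6% of counts in WT and 17.8% and 19.5% in KO), and so were 58 of 76 nuclear ones (adjusted p = 0.011). S phase genes (19 of 29 positive, adjusted p = 0.030) and type I interferon response genes (19 of 29 positive, adjusted p = 0.025) leaned the same way. NK receptor genes leaned lower, with 7 of 18 positive (adjusted p = 0.043). Adjusted over the list alone, 4 mitochondrial respiratory chain genes, 1 type I interferon gene and none of the other 4 lists were called. In the erythroid list all 9 genes were higher, with a median of 2.53 (adjusted p = 3.4e-07, or 0.59 with an estimated correlation), the list whose sum was highest in KO SLEC day 7 replicate 1.

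On day 14, 78 genes differed between KO and WT SLEC, 10 higher and 68 lower in KO, and 1803 had an unadjusted p under 0.05. *Il7r*, the receptor subunit for the survival cytokine IL-7, was at 27.1 ± 2.07 CPM in WT and 57.2 ± 20.5 CPM in KO (SD, n = 2), a log2 change of 1.10 ± 0.24 (SE, adjusted p = 0.0496). By convention SLEC are sorted as low for the protein of *Il7r*. The gates are not given in the sources used here, so a difference in sorting cannot be told apart from a KO effect. *Sntb1*, a syntrophin gene, rose by 1.18 ± 0.21 (adjusted p = 0.022), and the calcium pump gene *Atp2b1* by 0.68 ± 0.13 (adjusted p = 0.031). *Arhgap15*, which restrains Rac, rose by 0.84 ± 0.18 (adjusted p = 0.044), and *Mfsd14b* by 1.36 ± 0.17 (adjusted p = 0.0011). *mt-Nd6* rose by 0.75 ± 0.16 (adjusted p = 0.0496). Among the genes lower in KO, *Ctse* fell by 2.61 ± 0.19 (adjusted p = 8.9e-07) and *Ptprv* fell by 3.37 ± 0.35 (adjusted p = 1.3e-04). *Gramd1a*, *Ppm1j*, *Als2cl*, *Slc25a37*, *Ccnl1* and *H2-T10* fell by 0.89 to 1.54 (adjusted p 0.022 to 0.0496). The inhibitory Ly49 receptor gene *Klra9* fell by 1.99 ± 0.40 (adjusted p = 0.044) and the early response gene *Egr3* by 3.17 ± 0.58 (adjusted p = 0.022). *Zeb2* (0.44 ± 0.22), *Klrg1* (0.13 ± 0.19), *Tbx21* (0.20 ± 0.18), *Gzmb* (-0.15 ± 0.31), *Tcf7* (0.68 ± 0.64), *Bcl2* (0.39 ± 0.25), *Tnf* (-2.06 ± 0.53) and *Lef1* (1.26 ± 0.33) were not called.

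The genes lower in KO SLEC on day 14 included genes of B cells and myeloid cells. *Lyn*, a kinase of B cell receptor signalling, was at 38.65 ± 19.2 CPM in WT and 1.72 ± 0.287 CPM in KO (adjusted p = 0.040). *Irf5* was at 20.3 ± 10.5 and 4.73 ± 0.11 CPM (adjusted p = 0.031), and *Plcg2* was lower with a log2 change of -1.56 ± 0.32 (adjusted p = 0.044). *Cxcr5* (adjusted p = 0.023) and *Ifngr2* (adjusted p = 0.022) were also called. Of the 68 genes, 5 are in the lists of other cells, *Fcer2a* and *Ebf1* of B cells, *Csf1r* and *Mpeg1* of monocytes, and *Cxcr5* of CD4 T cells. *Cd40*, *Fcrl1*, *Fcrl5*, *Pou2af1*, *Siglecg*, *Spi1* and *Apoe*, picked out after their values were seen, were also lower. The median log2 change of the 68 was -4.95, or -4.73 with the 8 genes at 0 counts in KO set to their bound. With a term for B cell RNA, chosen after seeing the data, 5 genes were called and 1 of the 78 was shared: *Ctse*, at -2.81 (adjusted p = 0.012). *Il7r* was then at 1.33 (adjusted p = 0.90) and *Mfsd14b* at 0.67 (adjusted p = 0.94).

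The day 14 calls in SLEC depended on the libraries included. Leaving out a library of another group hardly bears on the sizes of these changes. The median log2 change of the 78 was -4.81 and -3.68 without WT SLEC day 14 replicate 1 or 2 (-4.51 with all libraries). It was -5.48 and -3.99 without KO SLEC day 14 replicate 1 or 2. In each of the 12 omissions 68 were lower, but the genes were chosen in these same libraries, so this is no separate support. *Ctse* and *Ptprv* kept their call whichever library was left out, and *Mfsd14b* lost it without KO SLEC day 14 replicate 2 alone (adjusted p = 0.067). The other 18 of the 21 named genes lost it in at least 1 omission. *Il7r* lost it without either library of KO SLEC day 7, WT SLEC day 14, KO SLEC day 14 or KO MPEC (adjusted p up to 0.38, without WT SLEC day 14 replicate 2). The count was 138 and 144 without WT SLEC day 7 replicate 1 or 2, and 38 without either KO SLEC day 7 library. It was 219 and 15 without WT SLEC day 14 replicate 1 or 2, 17 and 2 without KO SLEC day 14 replicate 1 or 2, and 29 without either KO MPEC library. By limma-voom 4 genes were called and by DESeq2 246, of which 3 and 54 were among the 78; the median change of the 78 was -4.64 by limma-voom and -4.57 by DESeq2.

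Of the T cell lists on day 14, 6 passed camera at the preset correlation in SLEC, but none with an estimated correlation (adjusted p 0.74 to 0.85) or by fry (0.40 to 0.63). KO SLEC were higher for all 7 mitochondrial respiratory chain genes, with a median of 0.54 (adjusted p = 5.4e-07); mitochondrial ribosomal RNA moved the same way, with 9.08% and 8.0% of counts in WT and 10.2% and 9.56% in KO. KO SLEC were lower for G2 and M phase genes (median -0.77, 2 of 30 positive, adjusted p = 1.0e-04), NK receptors (median -0.88, 5 of 18 positive, adjusted p = 0.0029) and cytosolic ribosomal proteins (median -0.20, 14 of 81 positive, adjusted p = 0.0085). Inhibitory receptors and *Tox* were lower, with a median of -0.99, or -0.82 with bounds (2 of 14 positive, adjusted p = 0.049), and T cell receptor signalling genes were slightly higher (median 0.09, adjusted p = 0.049). The NK receptor list shares *Tyrobp* and *Fcer1g* with the NK cell list of other cells, and WT SLEC day 14 held the most B cell and monocyte RNA. Whether RNA of other cells contributes to the T cell lists that were lower was not tested. Over all genes tested, 1 respiratory chain gene and 1 NK receptor gene were called, against 4 and 3 adjusted over the list alone; the other 4 lists had none by either count. Of the lists of other cells, B cells (adjusted p = 4.3e-15), monocytes and macrophages (6.0e-12), plasma cells (3.1e-04), neutrophils (3.1e-04), erythroid cells (0.0035), dendritic cells (0.0044) and NK cells (0.0090) were lower in KO. With an estimated correlation the monocyte list alone passed (adjusted p = 0.044), and B cells stood at 0.086. Adjusted over the list alone, 17 of 17 B cell and 10 of 13 monocyte genes were lower, against 2 and 2 over all genes.

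In MPEC on day 14, 2 genes differed between KO and WT, and both kept their call whichever library was left out. *Ctse* fell by 2.77 ± 0.18 on the log2 scale (SE, adjusted p = 1.7e-07) and *Synj2* rose by 2.40 ± 0.28 (adjusted p = 5.7e-04). *Mfsd14b* (0.87 ± 0.18, adjusted p = 0.55) was not called, nor were *Wdfy1* (-1.03 ± 0.24), *Ptprv* (-1.24 ± 0.34), the transferrin receptor gene *Tfrc* (-0.75 ± 0.25), *Ccs* (-0.90 ± 0.31), *Gtf2h2* (-0.68 ± 0.21) and *Ptpn13* (0.61 ± 0.20), each at an adjusted p of 1. The memory and effector genes *Il7r* (0.09 ± 0.20), *Tcf7* (0.07 ± 0.63), *Bcl2* (0.11 ± 0.24), *Id3* (0.79 ± 0.45), *Eomes* (-0.16 ± 0.52), *Zeb2* (-0.19 ± 0.24), *Tbx21* (0.10 ± 0.18), *Klrg1* (0.26 ± 0.53) and *Gzmb* (0.03 ± 0.33) were not called either. There were 355 genes with an unadjusted p under 0.05, below the 723 of chance, and 4 called genes without WT MPEC replicate 2. None of the 25 T cell lists passed camera. B cell genes (median -2.80, adjusted p = 2.1e-04) and monocyte genes (median -1.20, or -1.13 with bounds, adjusted p = 3.5e-04) were lower in KO. So were neutrophil (adjusted p = 0.016), erythroid (0.018) and NK cell genes (0.021), and none of these passed with an estimated correlation (adjusted p 0.23 to 0.45).

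Whether the KO effect differed between days or populations was tested directly. Between SLEC on day 14 and on day 7, 1 gene differed: *Ola1*, whose KO effect was lower on day 14 by a log2 difference of -3.85 ± 0.43 (adjusted p = 0.032). It was not called without WT SLEC day 7 replicate 1 (adjusted p = 0.60), KO SLEC day 7 replicate 1 (0.29) or 2 (0.52), or WT SLEC day 14 replicate 2 (0.068), and those fits called 0 genes. With the B cell RNA term, chosen after seeing the data, the difference was -4.81 (adjusted p = 0.28). The count was 91 without WT SLEC day 7 replicate 2, 12 without WT SLEC day 14 replicate 1, 3 without KO SLEC day 14 replicate 1 and 2 without WT MPEC replicate 1. There were 951 genes with an unadjusted p under 0.05. Between MPEC and SLEC at day 14, edgeR, limma-voom and DESeq2 called 0 genes, 612 had an unadjusted p under 0.05 in edgeR, and 3 were called without WT SLEC day 14 replicate 1. The higher *Il7r* in KO SLEC was therefore not shown to differ from the KO effect in the other populations. Across the 14460 genes, which are not independent replicates, KO effects correlated with a Pearson r of 0.03 (Spearman 0.01) between SLEC day 7 and SLEC day 14. The values were 0.02 (0.02) between SLEC day 7 and MPEC, and 0.29 (0.18) between SLEC day 14 and MPEC. The last rested on 1 library: r was 0.00745 without WT MPEC replicate 1, the MPEC library with the most B cell RNA (465.5 CPM), and 0.31 with the B cell RNA term. It was 0.0657 without a filter and 0.540 with the stricter filter.

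Genes called between WT MPEC and WT SLEC at day 14 leaned toward MPEC in KO SLEC on day 7. These sets were defined with the WT SLEC day 14 libraries, which hold the most B cell RNA. With the B cell RNA term 375 of the 1151 genes kept their call there, so the sets may hold genes of other cells. Of the 529 genes higher in WT MPEC than in WT SLEC at day 14, 64.1% had a positive KO effect on day 7, against 49.97% of all genes, with a median log2 change of 0.09 (adjusted p = 2.5e-05 by camera). Of the 622 genes lower in WT MPEC, 30.9% had a positive KO effect, with a median of -0.13 (adjusted p = 6.1e-05). With an estimated correlation the adjusted p was 0.13 for both. The first set lost its call without WT SLEC day 7 replicate 1 (median 0.04) or KO SLEC day 7 replicate 2 (0.00), and the second without the same libraries (-0.02 and -0.10). The genes that changed with day in WT SLEC did not pass in the KO effect in MPEC, with medians of -0.03 (adjusted p = 0.25) and -0.05 (adjusted p = 0.14). The set higher at day 14 passed without WT SLEC day 14 replicate 1 (-0.22) or WT MPEC replicate 2 (-0.06). The set lower at day 14 passed without WT SLEC day 7 replicate 2 (-0.07), WT SLEC day 14 replicate 1 (-0.05) or 2 (-0.11), or WT MPEC replicate 2 (-0.06).

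In WT SLEC, 678 of 14460 genes were higher and 759 lower on day 14 than on day 7. The granzyme gene *Gzmk* went from 161 ± 8.11 to 37.5 ± 2.70 CPM (SD, n = 2), a fall by 2.10 ± 0.18 on the log2 scale (SE, adjusted p = 5.5e-06), and *Gzma* fell by 1.53 ± 0.26 (adjusted p = 0.0032). The mitotic genes *Hmmr*, *Ube2c*, *Birc5*, *Ccnb2* and *Nusap1* fell by 4.46 to 4.99 (adjusted p at most 1.2e-04), and the replication genes *Pcna* (-1.34 ± 0.20, adjusted p = 3.8e-04) and *Tyms* (-1.89 ± 0.36) fell too. The respiratory chain genes *Cox5b* (-1.38 ± 0.16, adjusted p = 6.1e-05), *Cox5a* (-1.06), *Cox6b1* (-1.10) and *Uqcrfs1* (-0.97) and the ribosomal protein genes *Rplp0* (-1.15 ± 0.17), *Rps26* (-0.90) and *Rpl13a* (-1.33) also fell. The repressor genes *Bach2* (1.61 ± 0.22, adjusted p = 2.1e-04) and *Bcl6* (1.73 ± 0.27, adjusted p = 7.2e-04), which favour memory, rose with the survival gene *Bcl2* (1.65 ± 0.27, adjusted p = 0.0017). *Klra9* rose by 3.83 ± 0.46, *Rab6b* by 3.02 ± 0.30 and *Peg13* by 2.73 ± 0.31, and *Ola1* rose by 4.17 ± 0.33 (adjusted p = 5.2e-05). These genes kept their call whichever library was left out. *Klrg1* (-0.91, adjusted p = 0.0058) lost it without WT SLEC day 14 replicate 2 (0.099). *Mki67* (-3.99, adjusted p = 0.010) lost it without either WT SLEC day 14 library (up to 0.090). The B cell genes *Cd22*, *Cr2* and *H2-Aa* rose by 5.26 to 6.92 and lost their call in 6 to 9 omissions (adjusted p up to 0.14), the rise seen in the B cell sums. With the term for B cell RNA the change of *Klrg1* was 0.03, and those of *Cd22*, *Cr2* and *H2-Aa* were negative. The count of 1437 was 926 without WT SLEC day 7 replicate 2, and 749 and 413 without WT SLEC day 14 replicate 1 or 2. It was 382 with the B cell RNA term, 347 with a replicate block by day and 329 with only the groups compared.

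In KO SLEC, 1114 genes were higher and 1373 lower on day 14 than on day 7. *Gzmk* fell by 2.25 ± 0.19 (adjusted p = 1.8e-06) from 172 ± 29.5 to 35.8 ± 6.66 CPM (SD, n = 2), and the change was -1.81 for *Gzma* and -2.63 ± 0.51 for *Tnf* (adjusted p = 0.0018). *Mki67* fell by 4.81 ± 0.66 (adjusted p = 0.0041), and the log2 change was -3.58 ± 0.38 for *Cdk1*, -5.21 for *Cenpf* and -1.70 ± 0.22 for *Pcna*. *Cox7b* (-1.61 ± 0.18), *Cox5b* (-1.30), *Cox7a2* (-2.02 ± 0.28), *Rps26* (-1.30), *Rpl13a* (-2.22 ± 0.28) and *Rplp0* (-1.27) fell as well. *Bach2* (1.94 ± 0.24, adjusted p = 6.0e-05), *Bcl6* (2.02 ± 0.30, adjusted p = 2.6e-04) and *Bcl2* (2.01 ± 0.27, adjusted p = 3.0e-04) rose. *Il7r* rose by 1.48 ± 0.25 (adjusted p = 8.3e-04) and the effector factor gene *Zeb2* by 1.27 ± 0.23 (adjusted p = 0.0017), with *Runx1* (1.02), *Nfatc1* (1.06), *Tgfbr2* (0.79), *Zbtb20* (2.10) and the clock gene *Nr1d2* (2.53 ± 0.29). The integrin genes *Itgax* (-1.81) and *Itgam* (-1.18) and *Klrd1* (-1.22 ± 0.19) fell. These genes kept their call whichever library was left out. *Id2* fell by 0.58 ± 0.18 (adjusted p = 0.035), and lost its call without KO SLEC day 7 replicate 1 (0.15) or 2 (0.062), KO SLEC day 14 replicate 2 (0.37) or either WT MPEC library (0.051). *Gzmb* (-1.72, adjusted p = 0.0057) lost its call without either KO SLEC day 14 library (up to 0.055). The count of 2487 was 1415 without KO SLEC day 7 replicate 2, and 1430 and 875 without KO SLEC day 14 replicate 1 or 2. Of the genes called in each genotype, 323 were shared as higher (52.2 if independent) and 620 as lower (72.1), and across genes the day changes correlated with r = 0.37 (Spearman 0.49).

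The gene lists describe the day change in both genotypes. G2 and M phase genes were lower, with a median log2 change of -3.64 in WT (adjusted p = 2.7e-46, or 0.17 with an estimated correlation) and -4.80 in KO (3.9e-46, or 0.17). Of the 30 genes, 29 and 30 were called over all genes and 30 and 30 adjusted over the list alone. S phase genes had medians of -1.38 and -1.91 (adjusted p 2.6e-13 and 6.0e-15, or 0.50 and 0.38), with 11 and 18 of 29 called and 21 and 22 adjusted over the list alone. Nuclear respiratory chain genes had medians of -0.71 and -0.93 (1.5e-23 and 1.5e-22, or 0.17 and 0.19), with 38 and 50 of 76 called lower and 51 and 59 adjusted over the list alone. Cytosolic ribosomal protein genes had medians of -0.42 and -0.57 (1.5e-07 and 1.7e-09, or 0.51 and 0.41), with 7 and 23 of 81 called and 16 and 28 adjusted over the list alone. Cytotoxic genes (0.0048 and 0.0010, or 0.51 and 0.41) and cholesterol synthesis genes (0.0035 and 0.0059, or 0.50 and 0.41) were lower. Of these, 4 of 17 and 4 of 22 were called lower in WT, and 6 and 4 in KO; adjusted over the list alone it was 4 and 5 in WT and 7 and 4 in KO. Memory markers were higher (0.0048 and 0.0095, or 0.17 and 0.19), with 6 of 21 called higher in WT, and 9 higher and 5 lower in KO. Adjusted over the list alone, 7 were higher and 2 lower in WT, and 12 and 5 in KO. Mitochondrial respiratory chain genes (0.0069, or 0.54; lower) and NK receptors (0.018, or 0.50; higher) passed in WT and not in KO, and genes around *Id2* (0.038, or 0.23) and inhibitory receptors and *Tox* (0.024, or 0.38), both lower, passed in KO and not in WT. In the direct test between genotypes the adjusted p for these 4 was 0.56, 0.44, 0.15 and 0.0056 (0.81 to 0.85 with an estimated correlation). In these 4 lists, in this order, 1, 5, 6 and 4 genes were called in either direction, against 3, 7, 7 and 7 adjusted over the list alone. The share of mitochondrial ribosomal RNA in WT fell too, from 18.3% and 12.6% on day 7 to 9.08% and 8.0% on day 14. In KO it fell from 17.8% and 19.5% to 10.2% and 9.56%. No T cell list passed with an estimated correlation, and by fry 3 were called in WT and 11 in KO. Among lists of other cells, B cells (1.3e-08), plasma cells (0.0013), monocytes (0.0051) and neutrophils (8.2e-05) were higher on day 14 in WT, each at 0.22 with an estimated correlation, and erythroid genes lower in KO (0.013, or 0.89).

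MPEC and SLEC at day 14 differed in the genes that define them and in terminal effector, memory and NK receptor genes. In WT, 529 genes were higher and 622 lower in MPEC. By convention *Klrg1* and *Il7r* separate these cells in the sort, so their difference is no finding: *Klrg1* was at 142 ± 14.0 CPM in SLEC and 2.18 ± 0.517 CPM in MPEC (SD, n = 2), and *Il7r* at 27.1 ± 2.07 and 879 ± 169 CPM. *Gzma* fell from 988 ± 1.804 to 11.1 ± 2.12 CPM, a change of -6.46 ± 0.35 (SE, adjusted p = 3.8e-07), and *Gzmb* by 2.21 ± 0.33 (adjusted p = 0.0034). The effector and migration genes *Cx3cr1* (-3.14 ± 0.20, adjusted p = 1.7e-08), *Zeb2* (-3.21 ± 0.24, adjusted p = 1.6e-06), *S1pr5* (-3.41 ± 0.25), *Itgam* (-3.50 ± 0.27) and *Esm1* (-4.29 ± 0.22), the ectonucleotidase gene *Entpd1* (-2.22 ± 0.30) and the cytokine receptor genes *Il18rap* (-1.73) and *Il12rb2* (-1.63) were lower. The lymphoid homing genes *Ccr7* (2.88 ± 0.38), *Gpr183* (3.89 ± 0.30) and *Cxcr3* (3.17 ± 0.35) were higher, as were *Il6ra* (3.97 ± 0.36), *Socs3* (3.99 ± 0.44), *Ltb* (1.502 ± 0.18), *Slamf6* (2.19 ± 0.25), *Bcl2* (1.54 ± 0.24, adjusted p = 0.0017), *Myc* (2.75 ± 0.37), *Tox* (2.18 ± 0.33) and *Pdk1* (2.25 ± 0.20). The interferon-related genes *Slfn5* (2.48 ± 0.29), *Oas3* (1.85 ± 0.24) and *Rsad2* (2.26) and the ribosomal gene *Rps20* (1.42 ± 0.16) were higher too. These genes kept their call whichever library was left out. *Tbx21* (-0.83, adjusted p = 0.0072) lost it without WT SLEC day 14 replicate 1 or either WT MPEC library (up to 0.11). *Tcf7* (2.38 ± 0.66, adjusted p = 0.090), *Eomes* (1.26, adjusted p = 0.24) and *Id2* (0.06, adjusted p = 0.89) were not called. The count of 1151 was 655 and 414 without WT SLEC day 14 replicate 1 or 2, and 519 and 279 without WT MPEC replicate 1 or 2. With the term for B cell RNA, which was highest in WT SLEC day 14 (1018 and 3772 CPM), it was 477.

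In KO, 419 genes were higher and 320 lower in MPEC than in SLEC. *Klrg1* (-5.91 ± 0.31) and *Il7r* (4.01 ± 0.23) again followed the sort. *Gzma* was at 790.4 ± 22.5 CPM in SLEC and 6.62 ± 2.97 CPM in MPEC (SD, n = 2), a change of -6.89 ± 0.37 (SE), and *Cx3cr1* (-3.76 ± 0.20, adjusted p = 2.9e-09), *Zeb2* (-3.85 ± 0.25), *S1pr5* (-3.55), *Esm1* (-3.65), *Entpd1* (-2.26) and *Fasl* (-1.22) were lower. *Klra9* had 0 counts over KO MPEC and 247 over KO SLEC, which is at least 96.8-fold lower. *Id3*, an E protein inhibitor of memory cells, was at 8.82 ± 1.76 CPM in MPEC and 0.206 ± 0.292 CPM in SLEC (adjusted p = 0.0012). *Ccr7* (4.39 ± 0.53), *Gpr183* (3.91), *Il6ra* (4.63), *Socs3* (6.21 ± 0.67), *Ltb* (1.801), *Myc* (4.12 ± 0.45), *Tox* (2.21 ± 0.38), *Tnf* (3.18 ± 0.48), *Pdk1* (2.29), *Slfn5* (3.33 ± 0.32), *Oas3* (1.60), *Oasl2* (4.18) and *Rps20* (1.56) were higher. These genes kept their call whichever library was left out. *Tbx21* (-0.93, adjusted p = 0.0038) lost it without KO SLEC day 14 replicate 2 or KO MPEC replicate 1 (up to 0.099), and *Tcf7* (1.77 ± 0.65, adjusted p = 0.23), *Eomes* (0.83, adjusted p = 0.52) and *Id2* (0.23, adjusted p = 0.59) were not called. The count of 739 was 455 and 253 without KO SLEC day 14 replicate 1 or 2, and 356 and 381 without KO MPEC replicate 1 or 2. Between genotypes 290 genes were shared as higher (15.3 if independent) and 232 as lower (13.8), and across genes the differences correlated with r = 0.44 (Spearman 0.43).

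Of the T cell lists, 3 separated MPEC from SLEC in both genotypes with a preset and with an estimated correlation. The terminal effector and NK receptor lists hold *Klrg1*, and the memory and cytokine receptor lists hold *Il7r*. By convention both genes follow the sort, so these members are no finding. Terminal effector markers were lower, with 13 of 17 called in each genotype over all genes and adjusted over the list alone (adjusted p 5.7e-61 in WT and 2.3e-65 in KO, or 6.8e-04 and 5.9e-04). Memory markers were higher, with 13 of 21 called in WT and 13 higher and 1 lower in KO (4.7e-24 and 2.1e-22, or 6.8e-04 and 7.6e-04). Adjusted over the list alone it was 15 higher and 1 lower in WT, and 14 and 1 in KO. NK receptors were lower, with 11 and 6 of 18 called and 13 and 10 adjusted over the list alone (3.3e-22 and 6.7e-15, or 0.0083 and 0.021). The other lists passed camera at the preset correlation and not with an estimated one. By fry, which asks whether a list's genes move 1 way on balance without comparing them with other genes, 10 lists were called in WT and 9 in KO. Cytosolic ribosomal proteins were higher, with 34 and 39 of 81 called and 48 and 47 adjusted over the list alone (4.3e-30 and 7.9e-38, or 0.12 and 0.069). Ribosome biogenesis and *Myc* genes (6.8e-11 and 1.2e-11, or 0.086 and 0.067) and type I interferon genes (2.6e-10 and 6.1e-11, or 0.13 and 0.10) were higher. Of these 10 and 7 of 23, and 11 and 6 of 29, were called, against 15 and 12, and 18 and 15, as higher adjusted over the list alone. Mitochondrial (2.8e-07 and 0.038, or 0.19 and 0.61) and nuclear (3.2e-04 and 0.0015, or 0.59 and 0.61) respiratory chain genes and cytokine receptors (0.0016 and 5.7e-04, or 0.14 and 0.10) were higher, and cytotoxic genes lower (2.1e-05 and 0.0039, or 0.21 and 0.43). The mitochondrial ribosomal RNA share was also higher in MPEC, at 12.4% and 13.2% in WT and 11.0% and 13.8% in KO. T cell receptor signalling (0.041, or 0.68) passed in WT and not in KO, and inhibitory receptors and *Tox* (0.0050, or 0.16) and glycolysis (0.035, or 0.59) in KO and not in WT, all higher. In the direct test between genotypes the adjusted p for these 3 was 0.28, 0.0057 and 0.74 (0.95 to 0.97 with an estimated correlation). Over all genes and adjusted over the list alone, WT called 6 and 7 mitochondrial respiratory chain genes, 5 and 7 cytokine receptors as higher, and 6 and 7 cytotoxic genes as lower. KO called 5 and 5 cytokine receptors as higher and 4 and 5 cytotoxic genes as lower. Of nuclear respiratory chain genes 1 was called in WT, and 0 in KO by edgeR or adjusted over the list alone. The NK cell list was lower in both genotypes (7.3e-11 and 1.1e-08, or 0.0093 and 0.011), and it alone of the lists of other cells passed with an estimated correlation. In WT MPEC the lists of B cells (5.8e-05, or 0.34), plasma cells (0.0030, or 0.22), monocytes (1.2e-05, or 0.13), neutrophils (0.0015, or 0.28) and erythroid cells (0.045, or 0.43) were lower too.

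**Figure D4:**
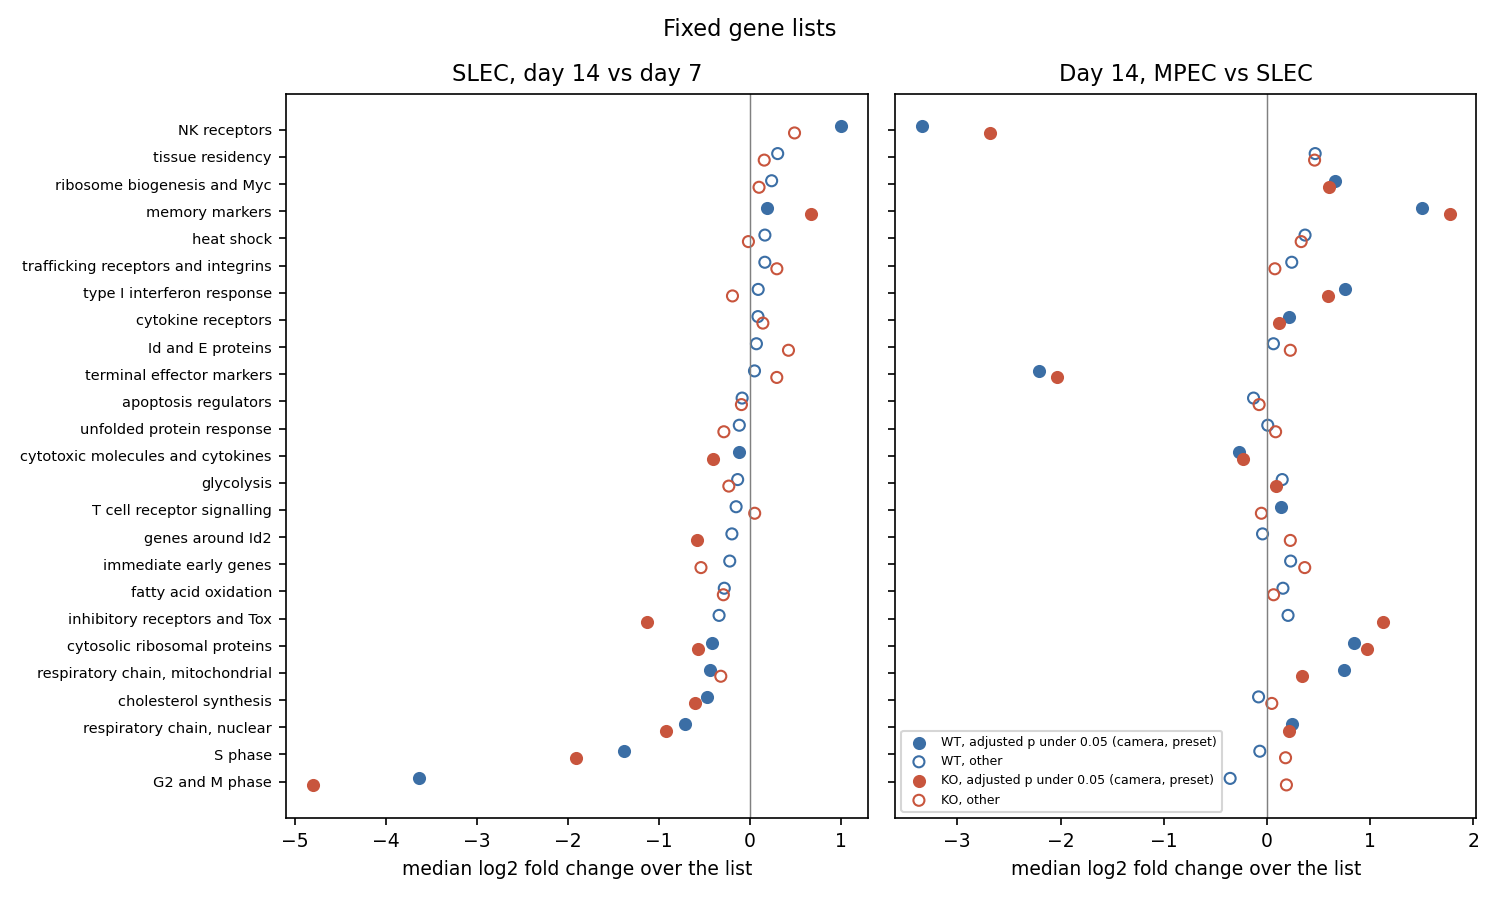
Median log2 fold change of each of the 25 T cell lists, WT in blue and KO in red, for SLEC day 14 against day 7 and for MPEC against SLEC at day 14; filled points passed camera with the preset correlation. G2 and M phase genes had medians of -3.64 and -4.80 for the day change.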

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

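The tests of other-cell RNA for the lower and the higher of the 12 genes, of linked variants for the 12, of an effect inside the T cells for the 68 genes and of exchanged labels for *Ola1* were chosen after the result was seen. The other tests were set beforehand.

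The KO effect differed between SLEC on day 14 and on day 7 for *Ola1*, by a log2 difference of -3.85 ± 0.43 (adjusted p = 0.032; -4.81 and 0.28 with the B cell RNA term), and this direct test is what drew attention to it. By the same test 5 lists had a lower KO effect on day 14 than on day 7. They were genes of G2 and M phase (adjusted p = 3.7e-10), S phase (0.0056), inhibitory receptors and *Tox* (0.0056), the nuclear respiratory chain (0.029) and cytosolic ribosomal proteins (0.031). Between MPEC and SLEC at day 14 the KO effect was lower in MPEC for the mitochondrial respiratory chain (0.0050) and higher for inhibitory receptors and *Tox* (0.0057). None of the 7 passed with an estimated correlation (adjusted p 0.81 to 0.97), and the tests were otherwise not taken further. In the first contrast 6 of 8 lists of other cells also had a lower KO effect on day 14: B cells (1.1e-15), monocytes (1.6e-09), erythroid cells (1.4e-08), plasma cells (8.6e-04), neutrophils (8.8e-04) and dendritic cells (0.017). In the second, B cells (6.7e-10) and monocytes (0.0013) had a higher one in MPEC. None of these passed with an estimated correlation (adjusted p 0.062 to 0.21, and 0.37), and by fry monocytes alone were called, in the first contrast (0.0496). Groups of 2 are too small to test for a single sample far from the others.

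The first pattern weighed is the 12 genes called in the mean KO effect. Chance is not excluded for their number. Of 100 splits within populations, drawn from 108, 4 called as many, the real one included (real 12, median of the others 0). Splits that mix the genotypes also put differences such as that of *Ctse* inside their groups, which can favour the real split. The highest others called 69, 15 and 13 genes, and the split with 69 points to a structure of the samples. That split parted replicate 1 from 2 on day 7 and in MPEC and WT from KO in SLEC day 14; it shared 0 genes with the 12 and 3 with the 68 lower genes of day 14, and its cause was not tested. RNA of other cells in the WT libraries of day 14 is argued against for the 6 lower genes as a set by their ratios between WT MPEC libraries. Their median log2 ratio of replicate 1 over 2 was 0.10 (-0.34 to 0.47), against 1.66 for the 68 genes below. Matched random lists ran from -0.23 to 0.27 from 5th to 95th percentile. The 6 higher genes it could only lower in WT by dilution. There, 21 T cell receptor signalling genes had a median change in SLEC day 14 of 0.0864 (75th percentile 0.29), against 0.75 or more for the 6. Since the 6 were chosen for a rise in a mean that holds SLEC day 14, this comparison cannot decide on dilution. With the B cell RNA term 6 of the 12 kept their call. In the other 6 the median size of the change went from 1.11 to 1.18 and the median SE from 0.15 to 0.24. Among them *Eps8l1* (-0.80 to -0.56), *mt-Nd6* (0.56 to 0.42) and *Ola1* (1.92 to 1.59) shrank, while *Wdfy1*, *Gm9522* and *Gm48904* did not. Variants linked to the knockout or to a marker locus cannot be told apart from an effect of losing Rroid2, since the mice's backgrounds are not given in the sources used here: 2 pairs of the 12 genes lie within 10 Mb (*Ctse* with *Ptprv*, *Synj2* with *Tmem181c-ps*), where random draws gave a median of 1 and a 95th percentile of 2 (permutation p = 0.132, one-sided), and within 10 Mb of *Ptprc*, the CD45 gene used as a congenic marker, 8.40% of 119 genes had an unadjusted p under 0.05, against 8.26% of all genes, and 2 (*Ctse* and *Ptprv*) were called, of 12 among 14460, while within 10 Mb of *Id2* it was 7.25% of 69 genes, and 1 (*Gm48904*) was called.

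The second pattern is the 68 genes lower in KO than in WT SLEC at day 14. If they come with RNA of other cells, they should also differ between the WT MPEC libraries, whose B cell sums were 465.5 and 145 CPM. Their median log2 ratio of replicate 1 over replicate 2 was 1.66, with 60 of 68 positive. Matched random lists had a 95th percentile of 0.24 (permutation p = 1e-04, the smallest that 10000 lists can give). That p is over draws of genes within a single pair of libraries and measures no spread between libraries. Between the WT SLEC day 14 libraries the median ratio of replicate 2 over 1 was 1.41, and the B cell list gave 3.78 and 1.97 in the same 2 contrasts, so RNA of B cells or other cells remaining in the sort is a candidate source for many of the 68. With a term for B cell RNA their median change went from -4.95 (median SE 0.94) to -1.02 (median SE 1.73), the larger error ending the calls along with the smaller change. An effect of the knockout inside the T cells on these genes therefore cannot be told apart; *Ctse* was called with the term in SLEC day 14, and *Ptprv* and *Als2cl*, also among the 68, were called with it in the mean (adjusted p = 0.0041 and 0.0050).

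The third pattern is *Ola1*, with 1027 and 1244 counts in the WT SLEC day 7 libraries and 22273 to 44492 in the other 10, where it ranked at 13 among tested genes by mean CPM. An exchange of labels with KO libraries is argued against by *Ctse*, which in the lower of these libraries was 5.51 times the highest KO value. Whether these libraries were prepared or sequenced apart from the others could not be decided. In them 2 genes (*Ola1* and *Ctnnd1*) had both libraries 4-fold or more outside the range of the other 10. The number was 20 for WT SLEC day 14, the group with the most B cell RNA, and 4 for KO MPEC. A smaller shift, or one that differs between replicates, would not show. The variance between replicates was largest in WT SLEC day 7, at 72.9 times that of counting error, a ratio that weighs genes with high counts most. No other tested gene within 1 Mb of *Ola1* was called. A biological difference of WT SLEC on day 7 may remain, as may a local effect on this gene that the counts do not resolve; neither was tested.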

How the results depend on the processing

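The B cell RNA term, protein-coding genes alone and the mean without SLEC day 14 were chosen after seeing the data; the other alternatives were planned. With DESeq2-style size factors every count of called genes stayed within 1.5 times its value.

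Without a filter on low counts the KO effect called 23 genes in SLEC day 7, 506 in SLEC day 14, 7 in MPEC and 167 in the mean, 109 for the difference between days and 23 for that between populations; this setting tests many more genes with few counts. With the stricter filter SLEC day 14 gave 51. DESeq2 called 246 in SLEC day 14, 5 in MPEC, 89 in the mean and 28 for the difference between days, limma-voom 4 in SLEC day 14, and the older quasi-likelihood 13 in SLEC day 14 and 2 for the difference between days. Fitting only the groups compared gave 2 in SLEC day 7, 329 for the WT day change and 1998 for WT MPEC against SLEC. Protein-coding genes alone gave 2 in SLEC day 7 and 27 in SLEC day 14, and the mean without SLEC day 14 gave 7. The B cell RNA term gave 5 in SLEC day 14, 0 for the difference between days by edgeR (951 genes at an unadjusted p under 0.05 without the term), 382 for the WT day change and 477 for WT MPEC against SLEC. Apart from the numbers of genes or libraries that these settings change, the cause was not tested.

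A block for replicate number gave 130 genes in SLEC day 14 and 2 for the difference between days. A block by day gave 49 in SLEC day 14, 347 for the WT day change and 1061 for the KO day change. Replicate numbers were not taken as pairs: across genes, replicate differences of 2 groups correlated between -0.164 and 0.207 over 15 pairs of groups, 5 of them above 0.1. KO SLEC day 7, WT MPEC and KO MPEC correlated with one another at 0.196 to 0.207, so a shared structure stays open.

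With 1 library left out, the counts ran from 2 to 198 in SLEC day 7, 2 to 219 in SLEC day 14, 2 to 4 in MPEC, 7 to 59 in the mean, 0 to 91 for the difference between days and 0 to 3 for that between populations. They ran from 413 to 1590 and 875 to 2979 for the WT and KO day changes, and from 279 to 1520 and 253 to 993 for WT and KO MPEC against SLEC. The correlation of KO effects ran from -0.16 to 0.15 between SLEC day 7 and SLEC day 14, -0.0948 to 0.0855 between SLEC day 7 and MPEC, and 0.00745 to 0.300 between SLEC day 14 and MPEC. With the stricter filter it was 0.0734 between SLEC day 7 and MPEC and 0.540 between SLEC day 14 and MPEC, and without a filter the latter was 0.0657. The medians of the WT MPEC signature in KO SLEC day 7 ran from 0.00243 to 0.155 and from -0.202 to -0.0212, and those of the WT day signature in KO MPEC from -0.218 to 0.0267 and from -0.122 to -0.0255. With an estimated correlation the first 2 (0.0869 and -0.132) no longer passed.

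Of 501 results for named genes, 369 were past the threshold. In a comparison of 2 groups most omissions take a library outside it. Genes named there for a large change had both libraries of 1 group beyond both of the other. A lack of reversals over the omissions is therefore largely fixed by the choice of genes. Over the 12 omissions 5322 gene values kept direction and side of the threshold, 662 lost the threshold, 28 gained it and 0 reversed. The B cell RNA term reversed 10, the only setting to reverse any: in the WT day change *Klrg1* (0.0293), *Tcf4* (-0.70), *Ralgps2* (-0.0716), *Cd22* (-0.12), *Wdfy4* (-0.39), *Cr2* (-0.0873), *H2-Eb1* (-0.98) and *H2-Aa* (-0.50), and in WT MPEC against SLEC *Scd1* (0.12) and *Ms4a1* (0.11). It also took 116 below the threshold, which includes the loss of precision that the term brings, as B cell RNA and WT SLEC day 14 largely coincide.

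With 2 libraries against 2, 41.8% of 2-fold changes were recovered on simulated data in SLEC day 14, so a gene not called there is not shown to be unchanged; depth and the number of libraries were not varied.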

Other observations

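In no comparison did camera pass 8 of the 25 T cell lists: apoptosis regulators, fatty acid oxidation, heat shock, Id and E proteins, immediate early genes, tissue residency, trafficking receptors and integrins, and the unfolded protein response. Terminal effector markers did not pass as a list in the KO day change (adjusted p = 0.82), although 6 of the 17 genes were called higher and 6 lower on day 14.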
